A study of Mus musculus with 45 samples.

How the data were processed

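Poly(A) RNA from mouse liver was sequenced in 45 libraries: Uhrf1hepKO livers (KO, a knockout of Uhrf1 in hepatocytes by its name) and wild-type livers (WT), at baseline and at 7 times after partial hepatectomy. Per the labels' protocols, the mice were C57Bl/6 and 8 to 12 weeks old, surgery took place in the morning, RNA was taken by a column kit that yields DNA and RNA from the same tissue, and libraries followed the Illumina TruSeq poly(A) protocol. Samples were grouped by genotype and time from their titles, which also give the replicate numbers. The labels do not say that the libraries of a group come from separate animals, so the p-values measure only the spread between these samples, which may be in part technical.

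The gene counts used for all main results are whole-number counts per gene as the authors deposited them, with 19966 Ensembl gene IDs and no normalization. The FPKM values (fragments per kilobase of transcript, scaled to library size) are a second deposited table of 46472 gene entries, 66 of them repeated IDs, and were used only as an alternative. Per the submitters' processing notes, the tools included FastQC 0.11.5, TopHat2 2.1.0 and Cufflinks 2.2.1, together with Trimmomatic, HTSeq and DESeq2 without a version, and the genome build was mm10. Their parameters, the gene annotation and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart by strand, and values of near-identical gene families (the Mup, Saa, Magea and Tuba3 genes, and Gstp1 with Gstp2) are uncertain where reads can match several members. Uhrf1 was counted over the whole gene, so transcripts that keep other exons, and cells other than hepatocytes, also add to its counts in KO livers. Gene symbols were matched by Ensembl ID, and 103 IDs had no symbol. Gene positions are 1-based and come from a reference of the GRCm38 (mm10) assembly.

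Total counts per library lay between 12.85 and 23.13 M (mega). The filterByExpr function of edgeR kept 14090 genes, which held at least 99.944% of the counts of every library. Counts were scaled with TMM factors, and levels are given as CPM with TMM scaling, as mean ± SD over the libraries of a group. The main test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, robust) with 1 mean for each of the 16 groups and no covariates. All 45 libraries shared the estimate of spread (29 residual degrees of freedom, prior degrees of freedom 5.94, common dispersion 0.0324). Fold changes are log2 values from that model, and their SE was computed from the fold change and its F statistic. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons were KO against WT at each of the 8 conditions, the mean of those 8 contrasts, each time against baseline within each genotype, and a joint F test of the 7 contrasts that compare the time courses of the genotypes. For Uhrf1, p-values were also adjusted over the 8 conditions.

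Before the data were examined, 37 gene lists were fixed (1014 symbols, of which 922 are in the count table). They covered DNA replication and S phase, G2 and mitosis, immediate early genes, G1 cyclins with kinases and inhibitors, p53 targets, growth factors and receptors, YAP targets, hepatocyte core genes, urea cycle and amino acid catabolism, cytochrome P450 and drug metabolism, bile acid synthesis and transport, fatty acid oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis, gluconeogenesis and glycolysis, acute phase, interferon-stimulated genes, germline genes silenced by DNA methylation, imprinted genes, oncofetal and liver tumour markers, Polycomb complexes, developmental transcription factors marked by Polycomb, DNA methylation and heterochromatin machinery, unfolded protein and integrated stress response, ribosome biogenesis, and the circadian clock. The remaining lists held markers of Kupffer cells, monocytes and neutrophils, lymphocytes, endothelial cells, stellate cells, cholangiocytes, erythroid cells, and exocrine pancreas or gut, with male-biased and female-biased liver genes and sex chromosome genes. Lists were tested with limma's camera on log2 CPM (prior count 3) with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. The same test with an estimated correlation was the alternative. For each list the members called over all genes tested and those adjusted over the list alone were counted.

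Named genes followed a rule fixed with the lists. Uhrf1 was always named. For KO against WT, the rule took the 8 largest log2 fold changes in each direction among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries compared. For the mean over conditions, it required the same direction in at least 7 of 8 conditions instead. For each time against baseline it took 5 in each direction, and for the joint test the 12 smallest p-values. Predicted genes and pseudogenes were counted but not named. Each list added its 4 members with the smallest p, and a fixed set of well-known regeneration genes was added as well. Genes named outside this rule are said to be so, and some genes that the rule names are not reported here.

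The alternatives fixed beforehand were DESeq2, DESeq2-type (RLE) scaling in edgeR, no filter on low counts, a fit of the compared groups only, replicate number as a block, limma on log2(FPKM + 1) for genes with FPKM of at least 1 in at least 2 libraries, and leaving out each library in turn. For the joint test, both genotypes at 30 h, 48 h and 7 days, the times with a group of 2 libraries, were also left out. Leaving out the 96 h libraries was added after the data had been seen. No covariate for sex was fitted, because all libraries expressed Y-linked genes. RLE scaling shifted the median log2 fold change of all genes by at most 0.029 from that with TMM.

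The tests were tried on simulated data made from the means and library sizes of these samples, with 100 genes changed 2-fold and 100 changed 4-fold. For KO against WT at baseline, among 13727 genes, edgeR recovered 51% of the 2-fold and 89% of the 4-fold changes with 5 false calls. DESeq2 recovered 54% and 92% with 9 false calls, and limma 53% and 88% with 5. For the mean over 8 conditions, with the changes placed in all KO groups, edgeR recovered 92% and 97% among 13736 genes with 8 false calls. For the joint test of the time courses, with the changes placed in KO at 40 h only, it recovered 35% and 78% among 13746 genes with 11 false calls. No effect of time was simulated, and single comparisons with a group of 2 libraries were not tried. Of 37 simulated lists of 40 genes, camera called the 1 list raised 1.5-fold and 0 of the 36 others, over 14090 genes. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera with the preset correlation makes false calls where list members vary together. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the package data.table (1.17.8), with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.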

Results

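Liver gene expression was measured by RNA sequencing in Uhrf1hepKO (KO) and wild-type (WT) mice, before and after partial hepatectomy, an operation that removes part of the liver and after which the remaining lobes regrow. UHRF1 binds hemimethylated DNA at replication forks and brings the maintenance methyltransferase DNMT1 to it. Livers were collected at baseline and at 24, 30, 40, 48 and 96 h, 7 days and 4 weeks after surgery. The design compares the genotypes at each of these 8 conditions, and each time with baseline within each genotype. Of the 16 groups, 13 held 3 libraries, and WT at 30 h, WT at 48 h and KO at 7 days held 2 each.

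Total counts (in M, mega) were 13.73 to 14.55 M per library in WT and 13.46 to 18.6 M in KO at baseline. After surgery they were 17.17 to 18.92 (WT) and 15.9 to 16.92 M (KO) at 24 h, 12.85 to 16.42 and 13.98 to 19.22 M at 30 h, 14.84 to 17.09 and 16.43 to 18.23 M at 40 h, and 17.29 to 17.45 and 17.09 to 20.68 M at 48 h. Libraries labelled WT and KO at 96 h held 14.36 to 18.69 and 16.6 to 18.14 M counts, those at 7 days 13.32 to 18.13 and 14.8 to 15.52 M. Those at 4 weeks held 14.9 to 23.13 and 14.06 to 20.29 M. Albumin took 4.91% to 8.05% of the counts in the group means of the other conditions, but 10.01% ± 2.61 (SD, n = 3) in the group labelled WT at 96 h and 16.66% ± 2.84 (n = 3) in the group labelled KO at 96 h. The first 3 principal components of log2 CPM held 39.7%, 11.1% and 7.8% of the variance. Levels below are mean CPM ± SD, fold changes are log2 ± SE, and n is 3 libraries per group unless stated.

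Uhrf1 (ENSMUSG00000001228; chromosome 17, 56303321 to 56323486, plus strand, mm10) was nearly silent in resting WT liver and rose strongly during regeneration. In WT it went from 0.415 ± 0.214 CPM at baseline to 3.02 ± 1.62 at 24 h, 32.3 ± 6 at 30 h (n = 2), 66.4 ± 39.6 at 40 h and 19.5 ± 0.448 at 48 h (n = 2). In KO livers it was 0.117 ± 0.124 CPM at baseline, 0.948 ± 0.237 at 24 h, 12.9 ± 3.49 at 30 h, 5.8 ± 2.81 at 40 h and 4.98 ± 2.07 at 48 h. KO was lower than WT at 40 h by the criterion over all genes (log2 −3.52 ± 0.5, edgeR adjusted p = 0.000314), with WT libraries between 27.5 and 107 CPM. When adjusted over the 8 conditions alone, edgeR also called the differences at 24 h (log2 −1.67 ± 0.62, adjusted p = 0.0203), 30 h (−1.33 ± 0.5, 0.0203), 48 h (−1.97 ± 0.52, 0.00251) and 7 days (−2.53 ± 0.86, 0.0154). At 7 days the libraries overlapped, with 0.543, 2.23 and 5.49 CPM in WT and 0.72 and 0.216 in KO. At baseline (−1.73 ± 1.31, adjusted p = 0.224) and 4 weeks (−0.49 ± 1.06, 0.649), edgeR found no difference, and both genotypes were under 0.5 CPM, so Uhrf1 could not check the labels there. At 96 h edgeR found no difference over the 8 conditions (log2 1.73 ± 0.83, adjusted p = 0.0608), with 0.27, 1.76 and 2.07 CPM in the libraries labelled KO and 0.148 to 0.792 in those labelled WT. These libraries overlap, so Uhrf1 could not check the labels at 96 h either. Fitted on the 6 libraries of 40 h alone, the 40 h difference was log2 −3.48 with an edgeR adjusted p of 0.291.

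**Figure D1:**
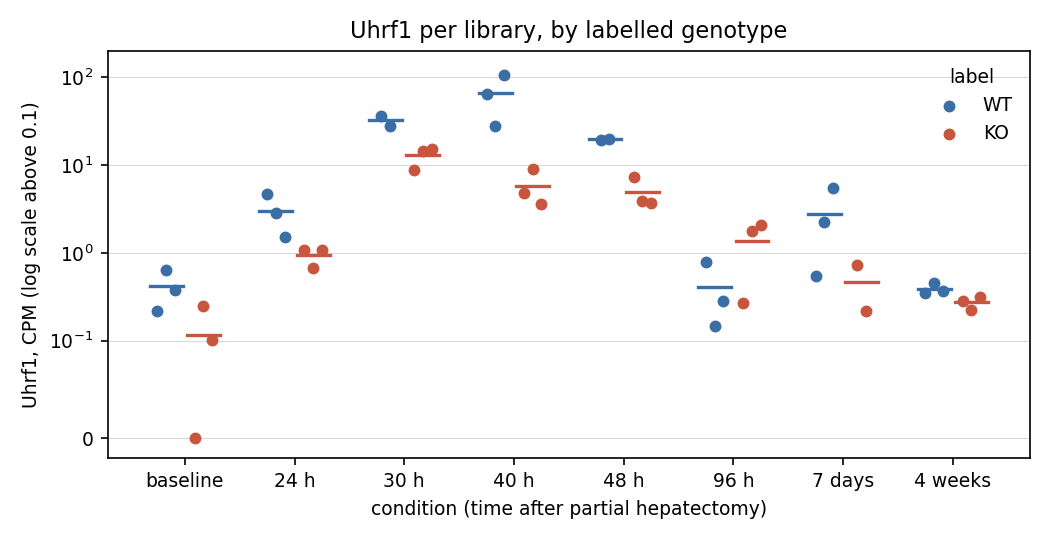
Uhrf1 counts per M (log axis, with 0 drawn at its foot) in each library at baseline and the 7 times after hepatectomy, WT in blue and KO in red, with bars at the group means. WT libraries peaked at 40 h (mean 66.4 CPM, KO mean 5.8), and at 96 h the libraries labelled KO had the higher mean (1.37 against 0.408 CPM).

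At baseline, a small set of genes that are silent or low in WT liver was active in KO liver. Bglap3, of the osteocalcin gene family (ENSMUSG00000074489; chromosome 3, 88368616 to 88372743, minus strand), stood at 10.9 ± 0.316 CPM in KO and 0.494 ± 0.332 in WT (log2 4.45 ± 0.52, edgeR adjusted p = 1.16e-05). Rhox5, an X-linked homeobox gene that DNA methylation keeps off in somatic tissue (ENSMUSG00000095180; X, 37804842 to 37808876, plus strand), stood at 3.48 ± 0.707 and 0.219 ± 0.144 CPM (log2 3.93 ± 0.75, edgeR adjusted p = 0.0163). Tmem200b (log2 2.45 ± 0.38), Ehbp1l1 (1.41 ± 0.25) and Pik3c2g (1.25 ± 0.26) were also higher, and Susd4 was lower (−1.54 ± 0.32). In all, edgeR called 12 genes at baseline, 11 higher and 1 lower, with 997 at an unadjusted p under 0.05. Of the 37 lists, camera called 11 at baseline, and 0 of these held with an estimated correlation (adjusted p = 0.536 for each). Among them were Kupffer cell markers (0 of 20 members called, camera adjusted p = 5.78e-05), lymphocyte markers (0 of 11, 4 adjusted over the list alone, camera adjusted p = 0.0017) and male-biased liver genes in the lower direction (0 of 17, 4 adjusted over the list alone, camera adjusted p = 0.000167). DESeq2 called 33 genes and limma on FPKM 24. The count fell to 4 without WT replicate 1, to 1 without WT replicate 3 and to 5 without KO replicate 2. Without WT replicate 3, Rhox5 had an edgeR adjusted p of 0.24.

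At 24 h the same genes led: Bglap3 was at 8.02 ± 1.61 CPM in KO and 0.294 ± 0.0724 in WT (log2 4.73 ± 0.55, edgeR adjusted p = 7.18e-06). Rhox5 was higher by log2 4.34 ± 0.71 (adjusted p = 0.00449). Unc119b, which carries lipid-modified proteins, was at 69.3 ± 1.5 and 43.8 ± 3.04 CPM (log2 0.66 ± 0.12, edgeR adjusted p = 0.0104). Pla2g16, a phospholipase, was higher by 0.93 ± 0.18 (0.033). The count at 24 h was 6 genes higher and 0 lower, with 473 genes at an unadjusted p under 0.05 by edgeR and 18 genes called by DESeq2. Interferon-stimulated genes stood higher as a list with 0 of 40 members called, also adjusted over the list alone (camera adjusted p = 2.48e-11, adjusted p = 0.376 with an estimated correlation). Cholesterol synthesis genes stood lower with 0 of 24 called either way (camera adjusted p = 4.09e-08, adjusted p = 0.559 with an estimated correlation). FPKM gave 16 genes and a fit of the 6 libraries alone gave 2. The count was 1 without WT replicate 2, 1 without WT replicate 3 and 3 without KO replicate 1. Bglap3 stayed past the threshold with each library left out.

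At 40 h, 18 genes were higher and 2 lower in KO livers by edgeR. They included Bglap3 (log2 3.79 ± 0.52, adjusted p = 0.000188), Rhox5 (3.71 ± 0.63, 0.00269), the glutathione S-transferase gene Gstp2 (ENSMUSG00000038155; chromosome 19, 4040285 to 4046023, minus strand; 9.8 ± 2 CPM in KO and 1.57 ± 0.303 in WT; 2.63 ± 0.44, 0.00211) and asparagine synthetase, Asns (22.1 ± 3.63 and 3.39 ± 0.59 CPM; 2.7 ± 0.44, 0.00185). Ehbp1l1 and Unc119b were higher (log2 1.15 ± 0.24 and 0.64 ± 0.12). Bahcc1 was lower (−1.1 ± 0.24, edgeR adjusted p = 0.0347). The list of germline genes silenced by DNA methylation held 55 symbols, of which 12 passed the filter on low counts. Of these 12, 2 were higher over all genes and 6 adjusted over the list alone (camera adjusted p = 4.78e-11, adjusted p = 0.00209 with an estimated correlation). Tuba3b, a testis tubulin gene with close copies, was at 1.17 ± 0.511 CPM in KO and 0 in all WT libraries. S-phase genes stood lower with 0 of 47 called either way (camera adjusted p = 6.64e-13, adjusted p = 0.274 with an estimated correlation). The count of 20 fell to 8 without WT replicate 1, 11 without WT replicate 3 and 12 without KO replicate 3.

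At 48 h (WT n = 2), edgeR called 18 genes higher and 1 lower. Gstp2 reached 17.7 ± 7.05 CPM in KO and 1.3 ± 0.374 in WT (log2 3.77 ± 0.53, edgeR adjusted p = 0.000163). Rhox5 (log2 5.03 ± 0.88), Bglap3 (4.91 ± 0.66), the chaperone regulator Bag2 (2.16 ± 0.46), Ehbp1l1 (1.19 ± 0.26), Unc119b (1.05 ± 0.14), the deubiquitinase Usp20 (1.01 ± 0.2) and the Polycomb gene Bmi1 (0.63 ± 0.14) were higher. Pyroxd2 was lower (−0.79 ± 0.17). Germline genes were higher (2 of 12, 4 adjusted over the list alone, camera adjusted p = 1.18e-18, adjusted p = 2.92e-05 with an estimated correlation). Tuba3b was at 1.08 ± 0.022 CPM in KO and 0 in both WT libraries. Endothelial cell markers stood lower with 0 of 20 called either way (camera adjusted p = 1.82e-11, adjusted p = 0.218 with an estimated correlation). A fit of the 48 h libraries alone called 0 of 13017 genes by edgeR, with 477 at an unadjusted p under 0.05. DESeq2 on all libraries called 25 and limma on FPKM 33. The count of 19 fell to 7 without WT replicate 2, 4 without WT replicate 3, 11 without KO replicate 1 and 9 without KO replicate 2.

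At 7 days (KO n = 2), 19 genes were higher and 0 lower in KO by edgeR, with 773 at an unadjusted p under 0.05. Rhox5 stood at 14.4 ± 3.62 CPM in KO and 0.185 ± 0.0947 in WT (log2 6.17 ± 0.73, edgeR adjusted p = 6.49e-06). Gstp2 (log2 4.15 ± 0.49), Bglap3 (3.81 ± 0.48), the non-coding RNA Snhg11 (2.65 ± 0.43), Asns (2.5 ± 0.45), Casc4 (1.58 ± 0.29) and the actin regulator Twf2 (1.27 ± 0.24) were higher. Col5a2, a chain of type V collagen, was at 23 ± 4.2 and 4.92 ± 0.605 CPM (2.22 ± 0.33, edgeR adjusted p = 0.000348). Germline genes were higher (2 of 12, 3 adjusted over the list alone, camera adjusted p = 2.97e-06, adjusted p = 0.0388 with an estimated correlation). Stellate cell markers stood lower with 0 of 22 called either way (camera adjusted p = 3.6e-06, adjusted p = 0.639 with an estimated correlation). The count of 19 was 7 in a fit of these libraries alone, 10 without WT replicate 2, 12 without WT replicate 3 and 9 without KO replicate 1. Asns had an edgeR adjusted p of 0.519 without KO replicate 3.

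At 4 weeks, 28 genes were higher and 3 lower in KO by edgeR. Rhox5 was at 13.7 ± 4.46 CPM in KO and 0.0995 ± 0.0917 in WT (log2 6.84 ± 0.74, edgeR adjusted p = 9.32e-07), Bglap3 at 14.5 ± 2.39 and 0.579 ± 0.286 (4.55 ± 0.49, 9.32e-07) and Gstp2 at 26 ± 13.2 and 2.53 ± 0.591 (3.38 ± 0.42, 1.52e-05). The elastase inhibitor Serpinb1a (log2 2.54 ± 0.46), the actin nucleator Diaph3 (2.48 ± 0.53), Snhg11 (1.92 ± 0.39), Asns (1.85 ± 0.41) and the NF-kappaB-inducing kinase Map3k14 (1.45 ± 0.28) were higher. Grk5, a kinase of G protein-coupled receptors (−1.33 ± 0.3), Klhl25 (−0.81 ± 0.18) and Cnksr3 (−0.81 ± 0.18) were lower. A clock score, chosen after the results were seen, was the mean log2 CPM of 4 Arntl arm minus that of 6 Dbp arm genes. This score was 1.36 ± 1.09 in WT and −0.88 ± 0.98 in KO, without overlap between the libraries. For genes that differed only at 4 weeks, genotype and hour of collection are therefore not told apart. Of the germline list, 2 of 12 were higher over all genes and 3 adjusted over the list alone (camera adjusted p = 7.15e-06, adjusted p = 0.0518 with an estimated correlation). Magea2 and Magea5, of an X-linked cancer-testis family with near-identical copies, were at 1.08 ± 0.755 and 0.662 ± 0.189 CPM in KO and 0 in all WT libraries. The count of 31 was 13 in a fit of these libraries alone, 12 without WT replicate 1, 7 without WT replicate 2, 17 without WT replicate 3 and 10 without KO replicate 3. Without WT replicate 1, Grk5 (edgeR adjusted p = 0.79) and Asns (0.372) lost their calls.

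Across the 7 conditions other than 96 h, Bglap3, Rhox5 and Xist were called in 7, Unc119b in 6, Gstp2 and the predicted gene Gm28321 in 5, and Ehbp1l1 and Xlr in 4, all higher in KO. The genes of this tally were chosen after their values were seen. Xist (ENSMUSG00000086503; X, 103460366 to 103483254, minus strand), the RNA that silences an X chromosome in female cells, ranged from 1.33 to 2.44 CPM in the KO group means and from 0 to 0.087 CPM in the WT group means of these 7 conditions. All libraries expressed Y-linked genes. Over all 8 conditions, 2043 genes were called in 1 condition, 73 in 2 and 14 in 3 to 7, and 0 were called in all 8. At 96 h as labelled edgeR called 2014 genes, against 6 to 132 at the other conditions. Most genes called in 1 condition therefore come from 96 h, and Bglap3, Rhox5 and Xist missed only 96 h. A signature score placed each library between the WT mean (0) and the KO mean (1) of the other conditions, 96 h always excluded. It used the 60 to 75 genes called in the mean of those conditions with an absolute log2 fold change of at least 1, without Uhrf1. It lay between −0.26 and 0.21 in the 19 WT libraries outside 96 h and between 0.59 and 1.47 in the 20 KO libraries outside 96 h. The 3 libraries labelled WT at 96 h lay at 0.64, 0.84 and 1.07. The 3 labelled KO lay at 0.91, 1.37 and 1.42. Bglap3 was at 17.2 ± 9.91 CPM in the libraries labelled WT at 96 h and Gstp2 at 11.2 ± 5.63, both above every other WT group.

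**Figure D2:**
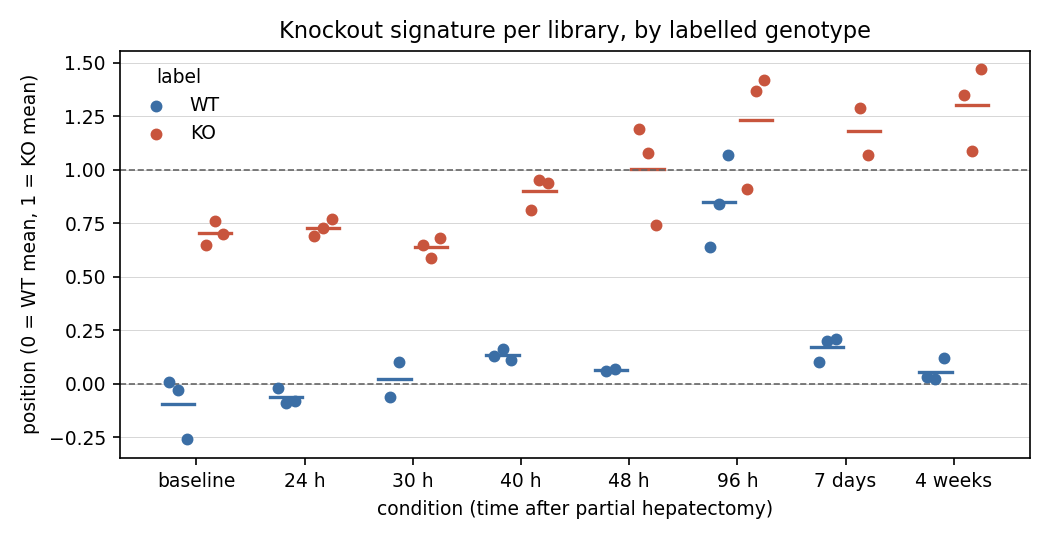
Position of each library between the mean of WT (0) and the mean of KO (1) libraries of the other conditions, 96 h always excluded. It covers genes called in the mean of those conditions with an absolute log2 fold change of at least 1, without Uhrf1. WT is in blue and KO in red, with bars at the group means. WT libraries outside 96 h lie between −0.26 and 0.21, and the 3 libraries labelled WT at 96 h lie at 0.64, 0.84 and 1.07, within the range of the KO libraries (0.59 to 1.47).

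At 30 h, genes of DNA replication and mitosis were higher in KO than in WT livers. Rrm2, a subunit of ribonucleotide reductase, was at 18.5 ± 5.8 CPM in WT (n = 2) and higher in KO by log2 2.45 ± 0.33 (edgeR adjusted p = 0.000242). Tyms (1.0 ± 0.15), Dut (0.98 ± 0.18) and Rrm1 (1.07 ± 0.23) of nucleotide supply were higher. Of the mitotic genes, Aurkb (1.99 ± 0.36), Prc1 (2.3 ± 0.42), Anln (2.17 ± 0.41) and the kinetochore gene Ska1 (3.32 ± 0.57) were higher. The S-phase list had 14 of 47 members called over all genes and 40 adjusted over the list alone, with a median log2 difference of 1.06 (camera adjusted p = 6.77e-36, adjusted p = 0.0428 with an estimated correlation). The mitosis list had 18 of 40 called and 37 adjusted over the list alone, with a median of 1.73 (camera adjusted p = 1.91e-36, adjusted p = 0.0516 with an estimated correlation). Of 24 p53 targets 3 were higher, 5 adjusted over the list alone (Gtse1 1.4 ± 0.32, Aen 0.69 ± 0.16, Eda2r 2.69 ± 0.66; camera adjusted p = 4.32e-05, adjusted p = 0.0428 with an estimated correlation).

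Among the other differences at 30 h, Rhox5 (log2 4.3 ± 0.91), Bglap3 (4.04 ± 0.66), Gstp2 (3.13 ± 0.56), Snhg11 (2.93 ± 0.53), the smooth muscle myosin Myh11 (3.44 ± 0.79) and Depdc1a (3.14 ± 0.73) were higher in KO. The protease inhibitor A2m was at 0.897 ± 0.325 CPM in KO and lower than in WT (−4.55 ± 0.99, edgeR adjusted p = 0.022). Il17rb (−0.88 ± 0.23), Tmem220 (−0.77 ± 0.2), Proz (−0.46 ± 0.12), C1s1 (−0.45 ± 0.11) and Copb2 (−0.41 ± 0.09) were also lower. Cholesterol synthesis genes stood lower, with 0 of 24 called over all genes and 18 adjusted over the list alone (camera adjusted p = 6.34e-17, adjusted p = 0.157 with an estimated correlation). Acute phase genes stood lower too (0 of 28, 2 adjusted over the list alone, camera adjusted p = 6.01e-08, adjusted p = 0.418 with an estimated correlation). In all, 123 genes were higher and 9 lower by edgeR, 89 and 4 of them by at least 2-fold. DESeq2 called 239 and limma on FPKM 276. Without WT replicate 3, edgeR called 0 genes, with 966 at an unadjusted p under 0.05. The count was 27 without WT replicate 2, 66 without KO replicate 2 and 47 without KO replicate 3. The median difference of the 87 S-phase and mitosis genes stayed between 1.05 and 1.41 with each library left out.

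**Figure D3:**
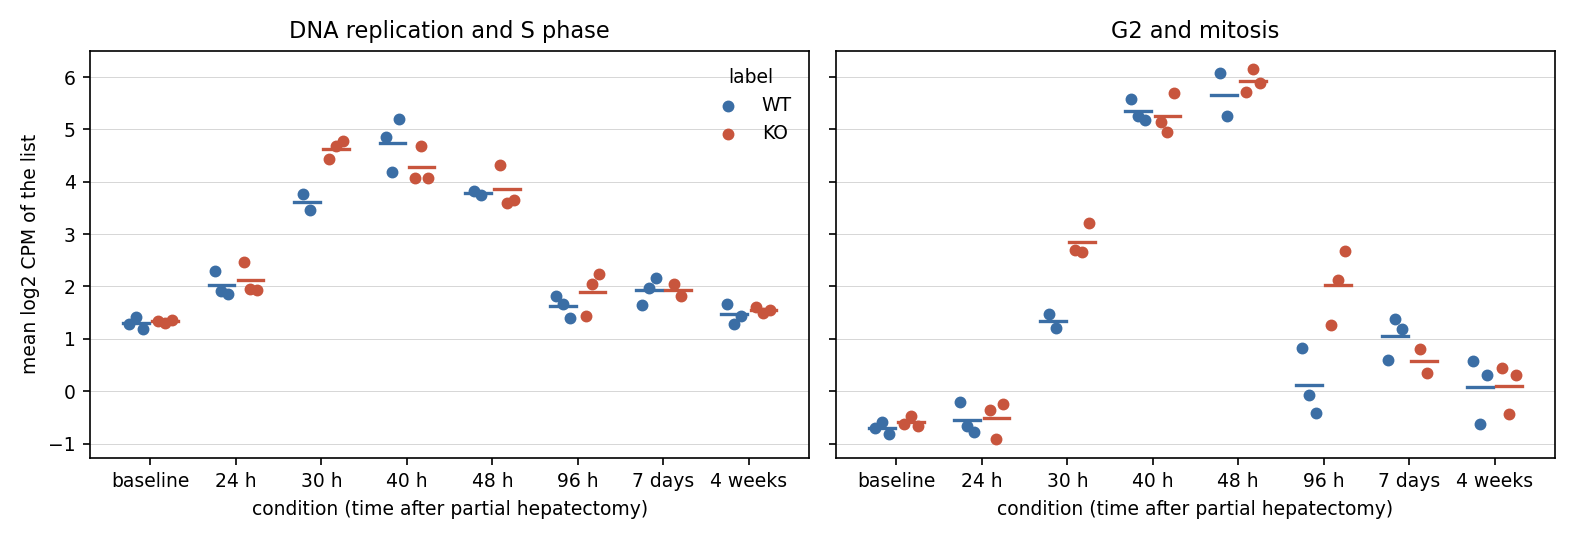
Mean log2 CPM of the S-phase list and of the G2 and mitosis list in each library at the 8 conditions, WT in blue and KO in red, with bars at the group means. At 30 h the KO libraries lie above the WT libraries (median difference 0.99 for S-phase and 1.61 for mitosis genes), at 40 h the medians differ by −0.43 and −0.1, and at 96 h the mitosis genes are higher in the libraries labelled KO (1.95).

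At 96 h most mitosis and acute phase genes were higher in the libraries labelled KO than in those labelled WT, and most male-biased genes were lower. Lipocalin 2 (Lcn2), an acute phase protein, was at 267 ± 137 CPM in the libraries labelled KO and 3.67 ± 1.3 in those labelled WT (log2 6.17 ± 1.15, edgeR adjusted p = 0.000659). Saa1 (5.4 ± 1.26), Saa2 (6.13 ± 1.49), the metallothionein Mt2 (974 ± 919 and 14.6 ± 9.57 CPM; 6.05 ± 1.31), Igdcc4 (5.87 ± 1.56), Psrc1 (5.37 ± 0.64) and the proteinase Prtn3 (35 ± 13 and 0.613 ± 0.384 CPM; 5.78 ± 0.72) were higher. Chil1 was at 1.1 ± 0.315 CPM and at 0 in all 3 libraries labelled WT. The lipogenic regulator Thrsp was at 715 ± 107 CPM in the libraries labelled WT and lower in those labelled KO (−2.79 ± 0.44, edgeR adjusted p = 0.000121). Mup21, a major urinary protein gene, was at 35.5 ± 8.84 and 515 ± 75.2 CPM (−3.86 ± 0.51, 1.87e-05). Mup19 (−2.88 ± 0.76), the male-biased steroid dehydrogenase Hsd3b5 (−2.64 ± 0.7), Derl3 (−2.79 ± 0.69) and Col27a1 (−2.56 ± 0.38) were lower as well, with Mup reads uncertain between family members.

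By list at 96 h, all 40 mitosis genes were higher in the libraries labelled KO, also adjusted over the list alone (Bub1b 2.38 ± 0.36, Racgap1 2.77 ± 0.42, Ccna2 2.58 ± 0.43; camera adjusted p = 5.94e-31, adjusted p = 0.0941 with an estimated correlation). Of 28 acute phase genes 20 were higher, 22 adjusted over the list alone (Fgl1 2.87 ± 0.4, Hpx 1.95 ± 0.31; camera adjusted p = 9.85e-17, adjusted p = 0.098 with an estimated correlation). Interferon-stimulated genes were higher in 14 of 40 cases, 28 adjusted over the list alone (Zbp1 2.19 ± 0.37; camera adjusted p = 9.09e-12, adjusted p = 0.116 with an estimated correlation). P53 targets were higher in 11 of 24, 14 adjusted over the list alone (Eda2r 3.44 ± 0.51, Phlda3 2.9 ± 0.43; camera adjusted p = 4.59e-10, adjusted p = 0.000831 with an estimated correlation). Oncofetal markers were higher in 7 of 18, 8 adjusted over the list alone (Spink1 4.81 ± 0.57, H19 6.07 ± 1.0; camera adjusted p = 7.89e-07, adjusted p = 0.00685 with an estimated correlation). Monocyte and neutrophil markers were higher in 6 of 14, 8 adjusted over the list alone (camera adjusted p = 5.16e-08, adjusted p = 0.0941 with an estimated correlation). Male-biased genes were lower in 11 of 17, 13 adjusted over the list alone (Slco1a1 −2.04 ± 0.23; camera adjusted p = 3.83e-10, adjusted p = 0.0941 with an estimated correlation). Ribosome biogenesis genes were lower in 16 of 34, 18 adjusted over the list alone (camera adjusted p = 2.54e-09, adjusted p = 0.152 with an estimated correlation).

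In all, edgeR called 1017 genes higher and 997 lower at 96 h, 516 and 176 of them by at least 2-fold. The signature above goes against the label WT here. No direction by genotype is drawn from the 96 h comparison on its own. The mean over 8 conditions and the joint test below include these libraries as labelled, so both are also given without them. The 2 groups also differ in the albumin share of their counts. Mitochondrial genes took 7.35% to 9.21% of the counts in these 6 libraries and at most 7.02% in the others. KO replicate 1 stands apart with 34.32% of its counts in 10 genes and a TMM factor of 0.661. A fit of these 6 libraries alone called 206 genes, of which 80.6% were higher, against 50.5% with all libraries. The count was 1330 without replicate 1 and 1244 without replicate 2 of the group labelled WT. Hsd3b5 had an edgeR adjusted p of 0.059 without KO replicate 2, Mup19 0.0584 without KO replicate 1, and Igdcc4 0.0501 without WT replicate 2.

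Averaged over the 8 conditions, with the 96 h libraries as labelled, 330 genes were higher and 113 lower in KO by edgeR. Among genes that the naming rule allows, with a mean log2 CPM of at least 1, Bglap3 (log2 3.8 ± 0.19, adjusted p = 8.09e-16), Rhox5 (4.37 ± 0.26, 1e-13) and Gstp2 (2.6 ± 0.17, 3.75e-13) led. They were followed by the estrogen sulfotransferase Sult1e1 (1.95 ± 0.37), Psrc1 (1.91 ± 0.38), Serpinb1a (1.74 ± 0.19), Asns (1.73 ± 0.16) and Mmd2 (1.72 ± 0.22). Larger log2 fold changes, such as those of Magea3 (5.59) and Xist (5.21), fell outside the rule. Lower in KO were Uhrf1 itself (−1.44 ± 0.3, edgeR adjusted p = 0.00335), Mup21 (−0.95 ± 0.17), Selenbp2 (−0.87 ± 0.21), Mup7 (−0.86 ± 0.21), Serpine2 (−0.75 ± 0.17), Susd4 (−0.73 ± 0.11), Bahcc1 (−0.64 ± 0.09) and the complement gene C4a (−0.61 ± 0.17). Without the 96 h libraries, an alternative chosen after the data were seen, edgeR called 331 genes (240 higher, 91 lower), 270 of them among the 443. There Bglap3 was higher by log2 4.33 and Gstp2 by 3.02. Psrc1 (1.42, adjusted p = 0.0618) and Mup21 (−0.53, adjusted p = 0.198) were no longer past the threshold. Psrc1 also lost its call without KO replicate 1 at 24 h (edgeR adjusted p = 1). Selenbp2 did without WT replicate 2 at 30 h (0.0565), and C4a kept its call in 18 of 45 fits that left out 1 library.

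Germline genes silenced by DNA methylation had the smallest adjusted p of any list in the average with an estimated correlation (3 of 12 higher, also adjusted over the list alone; Rhox5 4.37 ± 0.26, Magea2 5.38 ± 0.49, Magea5 4.54 ± 0.66; camera adjusted p = 1.01e-12, adjusted p = 0.0007 with an estimated correlation). Of the 55 symbols of this list, 38 are in the count table and 12 passed the filter on low counts. Genes silent in WT can pass that filter only through libraries that express them, mostly KO ones. The tested members are therefore in part selected for being high in KO, and the test does not speak for the rest. Without 96 h the germline list also held with an estimated correlation, and no other did (camera adjusted p = 0.000247). Higher with all 8 conditions and an estimated correlation were also p53 targets (5 of 24, 11 adjusted over the list alone, camera adjusted p = 1.59e-06, adjusted p = 0.00846), oncofetal markers (3 of 18, 5; Igf2bp3 1.91 ± 0.25, Ly6d 1.56 ± 0.31; 4.34e-05 and 0.0245) and female-biased liver genes (3 of 14, 9; Cyp17a1 1.32 ± 0.24; 4.64e-08 and 0.0245). Without 96 h, their camera adjusted p with an estimated correlation was 0.357, 0.536 and 0.1. Male-biased genes were lower (4 of 17, 4 adjusted over the list alone; Slco1a1 −0.46 ± 0.08; camera adjusted p = 6.02e-07, adjusted p = 0.234 with an estimated correlation). Cholesterol synthesis genes were lower too (2 of 24, 6 adjusted over the list alone; Idi1 −0.38 ± 0.1; camera adjusted p = 1.68e-09, adjusted p = 0.279 with an estimated correlation). In the fit without 96 h, 2 of 17 male-biased genes (4 adjusted over the list alone) and 4 of 24 cholesterol synthesis genes (12) were lower.

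Other lists that camera placed higher in the average lost the call with an estimated correlation. These were mitosis (4 of 40, 15 adjusted over the list alone, camera adjusted p = 8.89e-20; 0.184 with an estimated correlation), interferon-stimulated genes (4 of 40, 9; Bst2 0.4 ± 0.05; 3.32e-10; 0.234), S phase (2 of 47, 4; 1.01e-05; 0.485), monocyte and neutrophil markers (1 of 14, 3; 0.00982; 0.485), lymphocyte markers (1 of 11, 3; 0.011; 0.279), urea cycle (0 of 20, 2; 0.036; 0.591), imprinted genes (3 of 36 higher, with 7 higher and 1 lower over the list alone; Cdkn1c 0.58 ± 0.13, Rian 0.56 ± 0.15; 0.036; 0.116), G1 cyclins (2 of 17, 4; 0.0381; 0.234) and fatty acid oxidation (1 of 29, 3; 0.0402; 0.721). Endothelial markers stood lower (0 of 20 either way, camera adjusted p = 0.0384; 0.721 with an estimated correlation). Members called fell, without the 96 h libraries, to 1 of 40 for mitosis, 2 of 40 for interferon-stimulated genes and 1 of 47 for S phase, the same adjusted over the list alone, with camera adjusted p = 6.03e-06, 0.00028 and 0.000232. Imprinted genes had 2 of 36 higher, 5 adjusted over the list alone (0.0407). There, camera no longer called monocyte and neutrophil markers (adjusted p = 0.762), urea cycle (0.478), G1 cyclins (0.309), fatty acid oxidation (0.186), endothelial markers (0.0747) and lymphocyte markers (0.0574).

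The remaining lists were not called in the average of all 8 conditions. The camera adjusted p was 0.0565 for Kupffer cell markers (0 of 20), 0.0672 for immediate early genes (2 of 19 higher), 0.156 for the clock (0 of 20, 1 lower adjusted over the list alone), 0.182 for acute phase (0 of 28), 0.216 for gluconeogenesis (0 of 23), 0.236 for hepatocyte core genes (0 of 29), 0.245 for growth factors (0 of 23), 0.269 for Polycomb complexes (2 higher and 2 lower of 35) and for stellate cell markers (0 of 22), and 0.275 for DNA methylation machinery (0 of 37) and exocrine pancreas or gut markers (0 of 5, 1 higher adjusted over the list alone). It was 0.287 for erythroid markers (1 higher of 9), 0.426 for sex chromosome genes (1 higher of 5, Xist; median −0.08, mean 0.97), 0.448 for fatty acid synthesis (1 higher of 25), 0.505 for ribosome biogenesis (0 of 34), 0.593 for YAP targets (1 higher of 15), 0.596 for bile acid genes (1 higher and 1 lower of 22), 0.772 for developmental transcription factors (1 higher and 1 lower of 22), 0.89 for cytochrome P450 genes (4 higher and 1 lower of 37; median −0.03, mean 0.12), 0.922 for cholangiocyte markers (0 of 17, 1 higher and 1 lower adjusted over the list alone) and 0.924 for the unfolded protein response (2 higher of 23; median −0.04, mean 0.07). Adjusted over the list alone, the counts were the same in direction and at most 2 apart, as for cytochrome P450 genes (5 higher and 2 lower) and bile acid genes (2 higher and 1 lower). Without the 96 h libraries, camera called 5 of these lists, and none of them held with an estimated correlation. Fatty acid synthesis (4 of 25, also adjusted over the list alone; camera adjusted p = 0.00785; 0.263 with an estimated correlation) and ribosome biogenesis (0 of 34 either way; 0.0234; 0.65) stood higher as lists. Acute phase (0 of 28; 0.0133; 0.65), hepatocyte core genes (0 of 29; 0.0269; 0.6) and growth factors (0 of 23; 0.0269; 0.263) stood lower as lists, with no member called either way. Their median log2 differences were −0.19, −0.04 and −0.06.

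In WT livers, most acute phase genes rose in the first day after hepatectomy, and most cytochrome P450 and drug metabolism genes fell. At 24 h Lcn2 went from 4.03 ± 1.01 to 3060 ± 338 CPM (log2 9.57 ± 1.3, edgeR adjusted p = 2.65e-06). Saa1 went from 45.5 ± 11.9 to 10500 ± 1430 CPM (7.85 ± 1.4, edgeR adjusted p = 0.000113), and A2m rose by 7.7 ± 1.26. Reg3b was at 0 at baseline and 6.46 ± 1 CPM at 24 h. Thrsp fell from 1070 ± 458 to 8.03 ± 1.75 CPM (−7.05 ± 0.54, edgeR adjusted p = 2.13e-10). Upp2 (−6.19 ± 0.68), Rgs16 (−6 ± 1.26), Inmt (−5.7 ± 0.72) and the ion channel gene Hcn3 (−5.54 ± 0.43) also fell. Of 28 acute phase genes 24 rose (25 up and 1 down adjusted over the list alone, camera adjusted p = 1.82e-20, adjusted p = 0.156 with an estimated correlation). Of 37 cytochrome P450 and drug metabolism genes 24 fell and 3 rose (25 and 4 adjusted over the list alone; Ugt2b1 −2.58 ± 0.22; camera adjusted p = 1.71e-08, adjusted p = 0.176 with an estimated correlation). Fatty acid oxidation genes rose in 19 of 29 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 1.49e-07, adjusted p = 0.408 with an estimated correlation). Clock genes fell in 12 of 20 cases and rose in 3, 13 and 4 adjusted over the list alone (Per3 −4.08 ± 0.64, Cry2 −1.16 ± 0.18; camera adjusted p = 0.00226, adjusted p = 0.156 with an estimated correlation).

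At 30 h (n = 2), most S-phase genes had risen in WT livers. The replication licensing gene Mcm5 rose by log2 5.22 ± 0.56 (edgeR adjusted p = 8.21e-08). Cyclin D1 (Ccnd1) went from 10.6 ± 4.72 to 136 ± 23 CPM (3.67 ± 0.57, 2.39e-05) and Pcna from 21 ± 1.25 to 56.8 ± 15.4 CPM (1.43 ± 0.24, 3.69e-05). Aunip went from 0 to 2.8 ± 1.39 CPM. Of 47 S-phase genes 42 rose and 1 fell (45 and 1 adjusted over the list alone, camera adjusted p = 9.14e-41, adjusted p = 0.046 with an estimated correlation). Of 40 mitosis genes 30 rose, 32 adjusted over the list alone (camera adjusted p = 2.59e-23, adjusted p = 0.147 with an estimated correlation). Hamp2 (−5.86 ± 0.94), a hepcidin gene, and Mup2 (−4.62 ± 0.66) fell. In WT, edgeR called 1475 genes up and 1682 down at 24 h, and 1314 up and 1176 down at 30 h. The 30 h count of 2490 was 1537 in a fit of these groups alone, 1618 without WT replicate 2 and 1271 without WT replicate 3 at 30 h. Without the last, Rgs16 lost its call (edgeR adjusted p = 0.152).

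At 40 and 48 h, transcripts of S-phase and mitosis genes were raised in WT livers. The cyclin-dependent kinase Cdk1 went from 1.13 ± 0.29 CPM at baseline to 115 ± 9.08 at 40 h (log2 6.66 ± 0.46, edgeR adjusted p = 4.15e-13) and 143 ± 66.9 at 48 h (n = 2; 6.98 ± 0.48, 4.64e-13). Mki67 was at 227 ± 46.9 and 204 ± 54.3 CPM against 1.04 ± 0.634 at baseline. Hmmr rose by log2 9.22 ± 0.7 and 9.6 ± 0.72, and Ska1 and Cdc25c, at 0 in all baseline libraries, reached 6.9 ± 0.628 and 5.3 CPM at 40 h. All 40 mitosis genes rose at both times, also adjusted over the list alone (camera adjusted p = 1.72e-53 and 4.67e-62, adjusted p = 0.00967 and 0.0122 with an estimated correlation). S-phase genes rose in 46 of 47 cases at 40 h and 44 at 48 h, 46 at both adjusted over the list alone, and 1 fell at each (camera adjusted p = 1.48e-42 and 3.26e-30, adjusted p = 0.00967 and 0.0438 with an estimated correlation). P53 targets rose in 15 and 11 of 24 cases and fell in 2 and 1, the same adjusted over the list alone (Psrc1 7.41 ± 0.71 and 7.29 ± 0.74; camera adjusted p = 8.84e-06 and 0.000511, adjusted p = 0.00967 and 0.0474 with an estimated correlation). The DNA methyltransferase gene Dnmt1 rose by log2 2.72 ± 0.26 at 40 h.

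Of 29 hepatocyte core genes, 11 fell and 1 rose at 40 h, also adjusted over the list alone (camera adjusted p = 0.00436, adjusted p = 0.471 with an estimated correlation), and 14 fell at 48 h (14 down and 1 up adjusted over the list alone; camera adjusted p = 0.000314, adjusted p = 0.29 with an estimated correlation). Cebpa, a transcription factor of the mature hepatocyte, fell to 85.6 ± 19.4 CPM at 40 h (log2 −2.21 ± 0.2, edgeR adjusted p = 2.98e-11). Bile acid synthesis and transport genes fell in 14 and 13 of 22 cases at 40 and 48 h (1 rose at 40 h), 14 and 15 adjusted over the list alone (Slc10a1 −1.32 ± 0.15 and −1.63 ± 0.18; camera adjusted p = 2.51e-05 and 3.65e-08, adjusted p = 0.106 and 0.0278 with an estimated correlation). Male-biased genes fell in 14 and 12 of 17 cases, 14 at both adjusted over the list alone (Hsd3b5 −4.7 ± 0.77 and −6.07 ± 1.0; camera adjusted p = 6.48e-07 and 3.65e-08, adjusted p = 0.304 and 0.191 with an estimated correlation). Interferon-stimulated genes fell in 25 and 13 of 40 cases (1 rose at 48 h), 26 and 17 adjusted over the list alone (Ifit1 −2.98 ± 0.39 and −2.4 ± 0.42; camera adjusted p = 2.7e-06 and 0.000696, adjusted p = 0.411 and 0.524 with an estimated correlation). In WT, edgeR called 2703 genes up and 2443 down at 40 h, and 2205 up and 2168 down at 48 h. The 48 h count of 4373 was 2829 in a fit of these groups alone and 2606 without WT replicate 2 at 48 h.

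The libraries labelled WT at 96 h differed from WT baseline in 1807 genes upward and 2051 downward by edgeR. Among the largest increases were Bglap3 (17.2 ± 9.91 against 0.494 ± 0.332 CPM; log2 5.11 ± 0.52, edgeR adjusted p = 7.54e-08) and Rhox5 (5.73 ± 3.46 against 0.219 ± 0.144 CPM; 4.65 ± 0.73, 3.21e-05). Both marked KO livers at the other conditions. Diaph3 (3.36 ± 0.66), Hmmr (3.48 ± 1.05) and Kif15 (3.11 ± 0.93) rose. Igfbp5 (−2.61 ± 0.66), Myc (−2.4 ± 0.58), Cish (−2.37 ± 0.88), Ripor2 (−2.25 ± 0.56) and Arid5b (−1.98 ± 0.48) fell. Sex chromosome genes rose in 4 of 5 cases, also adjusted over the list alone, with Xist by 5.97 ± 0.82 (camera adjusted p = 0.00459, adjusted p = 0.304 with an estimated correlation). Unfolded protein response genes rose in 10 of 23 cases, also adjusted over the list alone (Hspa5 1.25 ± 0.24; camera adjusted p = 0.00459, adjusted p = 0.932 with an estimated correlation). Lcn2 (−0.12 ± 1.09, edgeR adjusted p = 0.95) and Cebpa (0.11 ± 0.19, 0.715) were not past the threshold. The count of 3858 was 1995 in a fit of these groups alone and 2161 without replicate 1 at 96 h. Without that library, Hmmr (edgeR adjusted p = 0.269) and Cish (0.16) lost their calls, and Kif15 had 0.052 without WT replicate 1 of baseline.

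At 7 days, 317 genes were up and 184 down in WT by edgeR. Spink1, an oncofetal marker, rose by log2 4.4 ± 0.69 (edgeR adjusted p = 0.000321), with Prtn3 (5.43 ± 0.77) and Lcn2 (413 ± 616 CPM; 6.68 ± 1.17). Mitosis genes rose in 19 of 40 cases and in all 40 adjusted over the list alone (Ccnb2 3.85 ± 0.72, Aurkb 3.29 ± 0.66; camera adjusted p = 8.59e-39, adjusted p = 0.042 with an estimated correlation). Monocyte and neutrophil markers rose in 7 of 14 cases, 11 adjusted over the list alone (S100a9 3.96 ± 0.92, Csf3r 2.56 ± 0.6; camera adjusted p = 1.84e-11, adjusted p = 0.042 with an estimated correlation). Oncofetal markers rose in 3 of 18, 4 adjusted over the list alone (camera adjusted p = 0.000128, adjusted p = 0.042 with an estimated correlation). Col27a1 (−2.69 ± 0.37), Thrsp (−2.58 ± 0.44), Slc17a8 and Mup21 fell. Saa1 (3880 ± 6100 CPM), Saa2 and Orm2 rose, but lost their calls without WT replicate 2 of 7 days (edgeR adjusted p = 0.141, 0.176 and 0.0635). Mup21 lost its call without the same library (edgeR adjusted p = 0.109), and Slc17a8 did without WT replicate 3 of baseline (0.142). The count of 501 was 71 in a fit of these groups alone, 164 without baseline replicate 3, 130 without replicate 2 and 291 without replicate 3 of 7 days.

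At 4 weeks, edgeR called 165 genes in WT, of which 61 were up and the others down, with clock genes in front. Npas2 rose by log2 3.88 ± 0.93 (edgeR adjusted p = 0.0303), and Per3 (−3.89 ± 0.63, 0.00125), Usp2 (−4.2 ± 0.71, 0.00195), Ciart (−4.76 ± 1.06, 0.0205) and Per2 (−2.2 ± 0.33, 0.000431) fell. The clock list had 10 of 20 members down and 1 up (12 and 2 adjusted over the list alone, camera adjusted p = 6.95e-07, adjusted p = 0.00516 with an estimated correlation). Asns (2.39 ± 0.5), Grk5 (2.1 ± 0.32), the heat shock gene Hspb1 (1.9 ± 0.32) and Tubb2a (1.9 ± 0.45) rose, and Cish (−3.99) and Hcn3 (−3.08 ± 0.35) fell. The count of 165 was 310 with DESeq2, 69 in a fit of these groups alone, 277 without the 96 h libraries, 73 without baseline replicate 3. It was 43, 59 and 49 without replicates 1, 2 and 3 of 4 weeks. Without replicate 1, Npas2 (edgeR adjusted p = 0.204), Tubb2a (0.155), Ciart (0.114) and Cish (0.145) lost their calls, and Asns had 0.081 without replicate 2.

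In KO livers at 24 h, Lcn2 rose from 3.87 ± 1.26 to 3350 ± 311 CPM (log2 9.75 ± 1.31, edgeR adjusted p = 1.86e-06) and Saa1 by 8.67 ± 1.45. Thrsp (−6.98 ± 0.54), Chrna4 (−7.15 ± 1.38), Hamp2 (−6.5 ± 0.82), Rgs16 and Upp2 fell. Reg3b and Retnla, at 0 at baseline, were at 13.5 ± 2.54 and 14 ± 9.92 CPM. Acute phase genes rose in 24 of 28 cases and fell in 1 (26 and 1 adjusted over the list alone, camera adjusted p = 2.19e-19, adjusted p = 0.307 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 24 cases (18 down and 1 up adjusted over the list alone, camera adjusted p = 7.01e-09, adjusted p = 0.445 with an estimated correlation). At 30 h, S-phase genes rose in 45 of 47 cases, also adjusted over the list alone (Mcm7 3.2 ± 0.21; camera adjusted p = 1.49e-51, adjusted p = 0.0137 with an estimated correlation). Mitosis genes rose in 39 of 40, all 40 adjusted over the list alone (Mad2l1 3.2 ± 0.25; camera adjusted p = 9.03e-37, adjusted p = 0.073 with an estimated correlation). Dsg1c (−6.09 ± 0.58) fell. In KO, edgeR called 1623 genes up and 1720 down at 24 h and 2394 up and 2264 down at 30 h.

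At 40 and 48 h in KO, Pbk rose by log2 8.44 ± 0.53 at 40 h, Ccnb1 from 0.245 ± 0.0378 to 128 ± 24.7 CPM at 48 h (9.01 ± 0.7, edgeR adjusted p = 6.66e-12) and Cdc20 from 0.465 ± 0.17 to 207 ± 25.8 CPM (8.74 ± 0.68). Troap and Ska1, at 0 at baseline, reached 5.44 ± 1.59 and 5.25 ± 1.37 CPM at 40 h. All 40 mitosis genes rose at both times, also adjusted over the list alone (camera adjusted p = 6.04e-57 and 4.46e-61, adjusted p = 0.00847 and 0.0134 with an estimated correlation). S-phase genes rose in 46 and 45 of 47 cases, 46 at both adjusted over the list alone, with 1 down at each (camera adjusted p = 2.78e-39 and 2.39e-31, adjusted p = 0.0142 and 0.0505 with an estimated correlation). Cholesterol synthesis genes fell in 16 and 22 of 24 cases and rose in 1 at each, 17 and 22 down adjusted over the list alone (Stard4 −1.2 ± 0.18 and −1.27 ± 0.18; camera adjusted p = 4.69e-06 and 1.38e-10, adjusted p = 0.524 and 0.268 with an estimated correlation). Nr1d1 (−5.26 ± 0.91), Clec2h (−5.6) and Fam198a (−5.04) fell at 40 h, and Serpina12 (−5.65) and Dbp (−5.55) at 48 h. EdgeR called 2525 genes up and 2495 down at 40 h and 2678 up and 2394 down at 48 h.

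The libraries labelled KO at 96 h differed most from KO baseline, with 3080 genes up and 3120 down by edgeR. Albumin (Alb) was at 215000 ± 74500 CPM against 64700 ± 3200 at baseline (log2 1.73 ± 0.23, edgeR adjusted p = 2.06e-07). The fatty acid synthase gene Fasn fell from 1430 ± 289 to 153 ± 112 CPM (−3.22 ± 0.43, 5.5e-07). Acute phase genes were still up in 21 of 28 cases, 23 adjusted over the list alone (Saa1 6.68 ± 1.34, Lcn2 6.1 ± 1.14; camera adjusted p = 3.06e-08, adjusted p = 0.554 with an estimated correlation). All 40 mitosis genes were up, also adjusted over the list alone (Cdk1 4.05 ± 0.47; camera adjusted p = 4.48e-21, adjusted p = 0.312 with an estimated correlation). P53 targets were up in 12 of 24 cases, also adjusted over the list alone (Ccng1 1.42 ± 0.17, Bax 1.3 ± 0.16; camera adjusted p = 0.00023, adjusted p = 0.129 with an estimated correlation). H19 rose by 4.23 ± 0.81 and Spink1 by 7.11 ± 0.71. Aacs, Rgs16 and Hcn3 (−3.8 ± 0.38) fell. A fit of these groups alone called 4122 genes.

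At 7 days (n = 2), 431 genes were up and 352 down in KO by edgeR. Eda2r (3.87 ± 0.66, edgeR adjusted p = 0.000644) and Gtse1 (2.44 ± 0.45, 0.00135), both p53 targets, rose. Stellate cell markers fell in 9 of 22 cases, 11 adjusted over the list alone (Ecm1 −1.79 ± 0.2, Dcn −1.22 ± 0.21; camera adjusted p = 1.24e-10, adjusted p = 0.229 with an estimated correlation). Endothelial markers fell in 5 of 20, 16 adjusted over the list alone (Eng −1.03 ± 0.24; camera adjusted p = 4.26e-09, adjusted p = 0.354 with an estimated correlation). Lcn2 rose to 200 ± 73.5 CPM (5.68 ± 1.15), and Ppp1r3b fell by 3.07 on the log2 scale. The count of 783 was 397 in a fit of these groups alone, 393 and 293 without baseline replicates 2 and 3, and 64 without KO replicate 3 of 7 days. Without that library Moxd1, Saa1, Saa2, Ska1, Gdf15, Dpt and Lpin1 lost their calls. Slc34a2 did without baseline replicate 2 (edgeR adjusted p = 0.597).

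At 4 weeks, 605 genes were up and 603 down in KO by edgeR. Gsta1, a glutathione S-transferase (log2 4.27 ± 0.9), and Mup17 (4.8 ± 1.09) rose, and Pls1 (−2.92 ± 0.44) and Hamp2 (−2.73 ± 0.62) fell. In all, 11 of 24 cholesterol synthesis genes fell, with 18 down and 1 up adjusted over the list alone (camera adjusted p = 1.44e-09, adjusted p = 0.496 with an estimated correlation). Endothelial markers fell in 11 of 20 cases, 16 adjusted over the list alone (Lyve1 −2.19 ± 0.51, Kdr −1.08 ± 0.27; camera adjusted p = 1.49e-09, adjusted p = 0.496 with an estimated correlation). The count of 1208 was 2167 in a fit of these groups alone. It lay at 605, 625 and 544 without baseline replicates 1, 2 and 3 and at 411, 726 and 445 without replicates 1, 2 and 3 of 4 weeks. Moxd1, Mup15, Saa1, Tff3, Adcy1 and Nipal1, which the rule also names here, lost their calls in 3 to 6 of these 6 fits.

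The changes against baseline had the same direction in both genotypes for nearly all genes that changed in both. No sham-operated group is among the samples. Effects of hepatectomy therefore cannot be told apart here from those of surgery as such or of the hour of collection, which both genotypes can share. Across the 14090 genes, which are not independent replicates, the log2 fold changes against baseline correlated with Pearson's r = 0.793 and Spearman's rho = 0.735 at 24 h, 0.719 and 0.649 at 30 h, 0.902 and 0.842 at 40 h, and 0.862 and 0.746 at 48 h. They correlated with 0.511 and 0.61 at 96 h as labelled, 0.459 and 0.425 at 7 days, and 0.42 and 0.433 at 4 weeks. The genotypes share no library. At 40 h, 3893 genes were called in both, all 3893 in the same direction, with 2063 up and 1830 down, where independent lists would share 484 and 433. At 96 h, 2842 of 2866 shared genes had the same direction, and at 4 weeks all 77 did.

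Time courses differed between the genotypes for 198 genes in the joint edgeR test, with 1933 at an unadjusted p under 0.05. Predicted genes aside, the 12 smallest p-values belonged to Spink1, Xist, Bglap3, Cdkn2c, Naip2, Tpmt, Gstp2, Hmgb2, Dhx33, Prtn3, Ifi27l2b and Hcn3. Cdkn2c, a cyclin-dependent kinase inhibitor, was at 13.5 ± 1.05 CPM in the libraries labelled KO and 4.19 ± 0.621 in those labelled WT at 96 h. Without the 96 h libraries 3 genes remained past the threshold: Diaph3, Naip2 and the predicted gene Gm15287, of which Diaph3 and Gm15287 are named after their values were seen. Naip2, an inflammasome receptor, was at 2.93 ± 0.0832 CPM in KO and 0.39 ± 0.158 in WT at baseline, and at 0.401 ± 0.179 and 1.52 ± 1.14 at 4 weeks. By list, camera called a genotype difference in the response that held with an estimated correlation for germline genes at 48 h (0 of 12 members either way, camera adjusted p = 7.93e-07; 0.0427 with an estimated correlation). P53 targets at 96 h as labelled did so too (3 of 24, 8 adjusted over the list alone; 1.12e-07; 0.00453). For S phase at 30 h, 1 of 47 members was called, 19 adjusted over the list alone (camera adjusted p = 1.88e-23, adjusted p = 0.205 with an estimated correlation). DESeq2 called 675 genes in the joint test. The joint count was 107 without WT replicate 3 at 30 h, 62 without WT replicate 2 and 82 without KO replicate 2 at 96 h, and it also fell more than 1.5-fold without WT replicate 1 at 96 h.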

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

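The tests of explanations and of sample splits in this part, and the fit without the 96 h libraries, were chosen after the results were seen, while the joint test was planned. The 12 genes below were picked out because their time courses differed between the genotypes in the joint edgeR test, and for most of them the difference lay at 96 h. Spink1 (edgeR adjusted p = 0.000205) was at 6.6 ± 4.72 CPM in the libraries labelled KO and 0.22 ± 0.147 in those labelled WT at 96 h, but at 0.275 ± 0.0189 in KO (n = 2) and 2.23 ± 0.493 in WT at 7 days. Xist (0.000205) was at 2.02 ± 1.54 CPM in the libraries labelled KO and 3.55 ± 2.57 in those labelled WT at 96 h, where WT groups of the other conditions stood near 0. Bglap3 (0.000248) and Gstp2 (0.000974) were at 17.2 ± 9.91 and 11.2 ± 5.63 CPM in the libraries labelled WT at 96 h. Cdkn2c (0.000556) and Hmgb2 (0.00106), a chromatin protein of dividing cells, were at 13.5 ± 1.05 and 22.2 ± 1.18 CPM in the libraries labelled KO and at 4.19 ± 0.621 and 6.5 ± 1.2 in those labelled WT at 96 h.

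Naip2 (edgeR adjusted p = 0.000889) was higher in KO at baseline (2.93 ± 0.0832 against 0.39 ± 0.158 CPM) and lower at 30 h (0.542 ± 0.349 against 2.65 ± 1.82, WT n = 2). Tpmt (0.000903), a methyltransferase of thiopurines, was at 72.7 ± 5.58 and 45.6 ± 4.42 CPM in the libraries labelled KO and WT at 96 h, Dhx33 (0.0015) at 13 ± 0.573 and 25.2 ± 2.79, and Prtn3 (0.0015) at 35 ± 13 and 0.613 ± 0.384. Ifi27l2b (0.0015), an interferon-induced gene, was at 39 ± 6.95 and 4.48 ± 1.03 CPM, and Hcn3 (0.00264) at 1.54 ± 1.18 and 9.43 ± 2.6. Without the 96 h libraries the edgeR adjusted p was 0.0105 for Naip2, and between 0.428 (Spink1) and 0.997 (Xist) for the other 11.

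The first pattern is that the libraries labelled WT at 96 h carried the expression signature of KO livers. Their lowest position between the WT mean (0) and the KO mean (1) was 0.64, above all 19 other WT libraries and within the range of the KO libraries, which fits wrong labels. No library labelled KO at 96 h lay in the WT range, so the data show no partner for an exchange within this time. A mixture with KO RNA and a response of WT livers at 96 h cannot be told apart from it. The lowest linear share of the KO level was 0.32 but these shares vary widely among true KO libraries too, and the highest position of WT libraries at 48 h and 7 days, the times on either side, was 0.21.

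The second pattern is the higher level of cell-cycle genes in KO livers at 30 h. A single library does not account for the median difference, which was at least 1.05 on the log2 scale with each library left out, but the members called fell to 0 of 87 without WT replicate 3, 6 without WT replicate 2 and 8 without KO replicate 3. A shift in collection time stays possible but has weak support. The clock genes of the Arntl arm against the Dbp arm differed between KO and WT by 0.99 at 30 h, although an earlier hour could shift them as well. Such a difference was not particular to 30 h: at 4 weeks this score was 1.36 ± 1.09 in WT and −0.88 ± 0.98 in KO. Within WT at baseline its SD was 2.31. An earlier entry of KO livers into the cell cycle stays open as a hypothesis. The median difference of S-phase genes, KO minus WT, was −0.43 at 40 h. There 0 of 47 members were called, the libraries overlapped, and camera did not call the list with an estimated correlation (adjusted p = 0.274). With 2 WT libraries at 30 h, these 2 explanations are not told apart.

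The third pattern is the clock genes among the changes of WT livers at 4 weeks. Another time of day at collection fits: the Arntl arm moved against the Dbp arm by 3.99 on the log2 scale. A lasting effect of the operation cannot be told apart from it, because no unoperated livers were collected beside those of 4 weeks. The difference between the arms was −2.34 ± 2.31 in WT at baseline (−3.79, −3.56 and 0.32), 1.36 ± 1.09 at 4 weeks and 2.63 ± 0.53 at 24 h, so the shift is not particular to 4 weeks. The same shift in KO was 0.68.

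Other splits of the same libraries were also fitted. For comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave the most calls (1 split) in KO against WT at baseline (12, highest other 5), 24 h (6, 1), 96 h as labelled (2014, 1585) and 4 weeks (31, 0). At 40 h, 2 splits reached the real count (20, highest other 26). The split with 1585 genes at 96 h shows that these samples also differ in ways other than their labels. Against baseline, the real split gave the most calls in WT at 24 h (3157, 1), 40 h (5146, 5), 96 h (3858, 115), 7 days (501, 1) and 4 weeks (165, 0). The same held in KO at 24 h (3343, 0), 30 h (4658, 0), 40 h (5020, 0), 48 h (5072, 1), 96 h (6200, 6) and 4 weeks (1208, 1). With 100 draws of genotype labels within conditions, 1 draw, the real one, called as many genes in the average (443, highest other 26). Redrawn labels thus seldom give so many calls, if the libraries come from separate animals, which the labels do not state. The draws included the 96 h libraries as labelled. In the joint test with all libraries the real labels also gave the most calls (198, highest other 163). These draws also remove the genotype difference shared by all conditions, so they cannot exclude chance for differing time courses. The joint count was below 163 in 13 of 45 fits that left out 1 library (lowest 62), and 3 without the 96 h libraries.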

How the results depend on the processing

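The fits without the 96 h libraries were added after the results were seen, and the other alternatives were planned. No result reversed. Of the counts of called genes, 119 stayed within 1.5 times of the main value under the alternatives other than leaving out 1 library and 29 did not; with 1 library left out, 166 did and 50 did not. Uhrf1 kept its side of the threshold in 32 of 33 fits of the other alternatives and in all 45 with 1 library left out. Among the single conditions it passed the threshold over all genes only at 40 h, so most of these fits kept a difference that was not called. The call at 40 h held in the 6 fits that left out a library of 40 h, and was lost in the fit of those libraries alone. The named genes' fold changes were tallied with DESeq2 and, for the average, also with RLE scaling and without the 96 h libraries. In these fits 258 were the same and 2 weaker. The tally does not cover the other alternatives, and the fit of the 48 h libraries alone called 0 genes for KO against WT. With 1 library left out many named genes lost their calls, as stated with each comparison. All 14 correlations between the genotypes' responses stayed. With 2 or 3 libraries per group, changes under 2-fold are often missed, and genes near 0 CPM carry little information.

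With DESeq2, KO against WT gave 33 genes at baseline, 18 at 24 h and 239 at 30 h, WT at 4 weeks gave 310 and the joint test 675. With limma on FPKM, KO against WT gave 24 at baseline, 16 at 24 h, 276 at 30 h, 33 at 48 h and 1183 at 96 h. Fits of the compared groups alone gave, for KO against WT, 2 at 24 h, 0 at 48 h, 206 at 96 h, 7 at 7 days and 13 at 4 weeks. For WT against baseline they gave 1537 at 30 h, 2829 at 48 h, 1995 at 96 h, 71 at 7 days and 69 at 4 weeks, and for KO 4122 at 96 h, 397 at 7 days and 2167 at 4 weeks. Uhrf1 at 40 h was −3.48 there and not called. Without the 96 h libraries, WT at 4 weeks gave 277 and the joint test 3, Psrc1 in the average was 1.42 and Mup21 −0.53. For all of these the cause was not tested. With an estimated correlation, 32 of 299 camera calls held in the comparisons of groups and the average, and 2 of 85 in the differences of response. The labels do not say that equal replicate numbers mark related samples, so the numbers were not taken as pairs. In 21 pairs of KO with WT, the correlations of equal numbers had a median of 0.089 (−0.306 to 0.306), and 8 were over 0.1. These values do not exclude pairing. The descriptions of the baseline libraries carry the name of the 40 h set, but for equal numbers of these 2 groups the correlations were 0.157, 0.09 and 0.102 in WT and −0.01, −0.064 and 0.159 in KO. With the replicate block, KO against WT gave 6 genes at baseline, 50 at 30 h and 9 at 7 days, and the joint test 61.

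With each library left out in turn, KO against WT gave 1 to 18 genes at baseline, 1 to 5 at 24 h, 0 to 122 at 30 h, 8 to 19 at 40 h, 4 to 21 at 48 h, 1244 to 2444 at 96 h, 9 to 15 at 7 days and 7 to 39 at 4 weeks. Where WT at 30 or 48 h or KO at 7 days had 1 library left, that library was assumed to vary like the other groups. For WT against baseline the counts were 1271 to 2086 at 30 h, 2606 to 3996 at 48 h, 2161 to 4246 at 96 h, 130 to 563 at 7 days and 43 to 133 at 4 weeks. For KO they were 64 to 831 at 7 days and 411 to 726 at 4 weeks. The joint test gave 62 to 286.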

Other observations

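The genes in this part come from planned lists and comparisons, and the points on Unc119b and albumin were chosen after the values were seen. Markers of the cells around the hepatocytes also differed over time. Marco, a scavenger receptor of macrophages, went from 3.33 ± 1.8 to 54.1 ± 41.9 CPM in WT at 7 days (log2 4.02 ± 0.86, edgeR adjusted p = 0.0066). Kupffer cell markers rose there in 2 of 20 cases, 15 adjusted over the list alone (camera adjusted p = 2.23e-09, adjusted p = 0.299 with an estimated correlation). In KO at 4 weeks the lymphatic and sinusoidal receptor gene Lyve1 fell from 13.6 ± 2.1 to 2.99 ± 0.49 CPM, and the stellate cell genes Reln (−1.08 ± 0.25) and Ecm1 (−0.73 ± 0.17) fell. Stellate cell markers fell in 7 of 22 cases, 14 adjusted over the list alone (camera adjusted p = 6.63e-07, adjusted p = 0.496 with an estimated correlation). The change of the stellate list from baseline stood lower in KO than in WT at 7 days and 4 weeks, with 0 of 22 members called at either time and 3 and 0 adjusted over the list alone (camera adjusted p = 4.41e-10 and 6.24e-10, adjusted p = 0.367 and 0.368 with an estimated correlation).

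Fatty acid oxidation genes rose in KO at 24 h in 22 of 29 cases and fell in 1 (23 and 1 adjusted over the list alone, camera adjusted p = 4.32e-15, adjusted p = 0.307 with an estimated correlation). Genes of ribosome biogenesis rose in KO at 30 h in 13 of 34 cases, 14 adjusted over the list alone (camera adjusted p = 6.52e-05, adjusted p = 0.592 with an estimated correlation). Interferon-stimulated genes fell in KO at 30 h in 21 of 40 cases and rose in 1 (25 and 1 adjusted over the list alone, camera adjusted p = 3.13e-06, adjusted p = 0.549 with an estimated correlation).

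Unc119b stood at 58.6 ± 3.94 CPM in the libraries labelled WT at 96 h, and between 35.2 and 43.8 CPM in the means of the other WT groups. The 10 most abundant genes took 29.63% ± 4.07 of the counts in the libraries labelled KO at 96 h and 23.44% ± 2.99 in those labelled WT.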
